A study of Homo sapiens with 6 samples.

How the data were processed

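RNA from LP-1, an established human multiple myeloma cell line, was sequenced in 6 libraries. Of these, 3 came from cells in which RNF5 had been depleted with a short hairpin RNA and 3 from cells with a non-target control. Per the labels, the cells grew in RPMI-1640 with 15% serum, RNA was taken up in Trizol and libraries followed a standard Illumina preparation. The number of hairpins used, the time between transduction and harvest, and whether the 3 libraries of a group were separate cultures are not given in the sources used here. The p-values below therefore measure only the spread between these 6 libraries.

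The deposited table held a selected set of 1877 genes and not a full expression table. Every listed gene had an absolute log2 fold change of at least 1 (smallest 1.0002) and an adjusted p-value under 0.05 (largest 0.0499), both as deposited by the authors. Per the file headers, each gene had a value in each library, the 2 group means, a fold change, its log2 and a p-value with its adjusted form. Per the submitters' processing notes, Bowtie 0.12.2 and the human genome build hg19 were used. The notes do not say for which step. The per-library values deposited by the authors were a normalized signal of a scale that is not given in the sources used here, written with 2 decimals and not as whole numbers. The group means were the means of the 3 library values. The fold ratio that the authors deposited was the knockdown over the control, and the log2 value deposited by the authors was its logarithm. The test behind the p-value deposited by the authors is not given in the sources used here.

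The ratio of the library means and the deposited fold change differed, by an amount that varied between genes. Over 431 genes with both group means at least 5, the log2 ratio of the means exceeded the authors' log2 value by a median of 0.173 (quartiles 0.111 and 0.220). The deposited fold changes were therefore not made from the means of the values per library alone. All fold changes given here come from the values per library unless the authors are named, and should be read against this median shift of 0.173, which does not describe each gene. In 7 of the 1877 genes the library means went against the deposited direction, and 3 genes were listed at 0 in every library.

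The values were not counts and could not be turned back into whole reads, so the sequencing depth of each library is unknown and no counting interval is given. A count-based test, the first choice before the data were examined, was replaced by limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1). A fold change on that scale understates the change of genes with low values. Genes entered the fit with a value of at least 1 in 3 or more libraries, which kept 1290 and left out 587. The design held the group alone. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, and as changed at least 2-fold with also an absolute log2 fold change of 1 or more. Because the authors had chosen the genes on these same libraries, neither the counts nor the p-values are independent evidence of a change. Genes outside the list have no values here and cannot be called unchanged. RNF5 and DNAJA1 also had an exact 2-sided permutation test, which cannot give a p under 0.1 with 3 against 3.

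Before the data were examined, 41 gene lists with 1166 distinct genes were fixed, 36 of pathways and 5 of markers of other cell types. Of those genes, 111 were in the authors' set. The planned set test compares a list with all expressed genes and was not run on a selected set. In its place, chosen after the data were seen, Fisher's exact 2-sided test compared the directions of a list's changed members with those of all other changed genes, for lists with at least 5 changed members and with Benjamini-Hochberg adjustment over the 6 lists that reached that number. Genes do not vary independently, so these p-values are too small to an unknown degree. The other changed genes also included non-coding RNAs and pseudogenes, which the authors listed mostly as higher. Their protein-coding genes were more often lower (752 against 516 higher). The p-values of lists of protein-coding genes that fell may therefore partly reflect gene class, and no test within a class was run. The genes named were RNF5 and DNAJA1, the 12 largest rises and the 12 largest falls, and up to 4 members with the smallest p of each list with at least 3 changed members. The largest rises and falls were taken among changed genes with a name whose groups did not overlap and whose mean was at least 5. For each list of other cell types, up to 2 members with the highest mean were named. Any other gene named was chosen after its values were seen. RNF5P1, RNF185 and XPO1 were to be named as well but were not among the listed genes.

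Gene names came from the table and from a table of gene identifiers. Lengths and gene classes came from GENCODE release 29 by identifier, which matched 1721 genes (91.7%). No coordinates are printed, because the table held none. No gene name was given for 336 genes. The test was checked on simulated values for the knockdown comparison with 1216 genes. It recovered 78.8% of 99 genes changed 2-fold and 100% of 100 genes changed 4-fold, and 11 of 189 calls (5.82%) were false. The simulated noise was independent between genes and most simulated genes were unchanged. The listed genes were selected as changed and shift together within a library, so this false share does not describe the real calls. Other pseudocounts (0.1 and 5), no filter, a stricter threshold, a replicate block and leaving out each library in turn were planned. A rescaling by the median offset from the authors' fold changes and the removal of a length trend were added after the data were seen. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the tables, Fisher's tests and plots.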

Results

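Gene expression was compared between LP-1 myeloma cells depleted of RNF5 (n = 3 libraries) and LP-1 cells with a non-target control (n = 3). RNF5 encodes a membrane-anchored ubiquitin ligase of the endoplasmic reticulum, and the study's title links it to the co-chaperone DNAJA1, to mitochondrial function and to selinexor, an inhibitor of the nuclear exporter XPO1. Values are normalized abundances of 1877 genes that the authors had selected as changed, of which they listed 924 as higher and 953 as lower in the knockdown. The values of these genes summed to between 90825 and 93975 in the control libraries and between 116843 and 122079 in the knockdown libraries. These sums cover the selected genes alone and are not a depth, which is unknown. Listed genes at 0 numbered 22, 18 and 27 in control libraries 1, 2 and 3, and 114, 97 and 98 in knockdown libraries 1, 2 and 3. Values are given as mean ± SD of 3 libraries, and all adjusted p-values of single genes come from limma. For each gene named below with a rise or fall, the 3 knockdown values all lay on one side of the 3 control values.

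RNF5 (ENSG00000204308) was lower in every knockdown library than in every control library. Its abundance was 95.40, 81.35 and 88.44 in the knockdown libraries and 1595, 1649 and 1248 in the control libraries. The mean fell from 1497 ± 218 to 88.4 ± 7.03, which left 5.90% of the control level (log2 fold change -4.06, SE 0.16, limma adjusted p = 1.34e-08). DNAJA1 (ENSG00000086061), a co-chaperone of the cytosolic HSP70 proteins, fell 2.13-fold, from 81.9 ± 11.2 to 38.4 ± 2.75 (log2 fold change -1.07, SE 0.17, limma adjusted p = 0.000145). DNAJA1 is also a member of the heat shock list described below, which fell as a group. The authors' own log2 fold changes were -4.24 for RNF5 and -1.28 for DNAJA1. The exact permutation test gave p = 0.1 for each gene, the smallest value that 3 against 3 libraries allow. Reads of RNF5 and of its near-identical processed pseudogene RNF5P1 cannot be told apart here, and RNF5P1, the related ligase RNF185 and XPO1 were not among the listed genes.

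TXNIP, which binds thioredoxin and restrains glucose uptake, rose from 2.06 ± 0.490 to 43.4 ± 3.43 (21.1-fold, log2 fold change 3.87). Among genes with a name and a mean of at least 5, this was the largest rise on the log2(value + 1) scale. That scale understates low genes, and by the ratio of means EGR1 rose more (49.8-fold, from below 1). With a pseudocount of 0.1, HMGA1P8 (4.93) passed TXNIP (4.36). The chemokine receptor CCR1 rose 6.76-fold to 49.1 ± 3.88, the integrin subunit ITGB7 rose 4.87-fold from 351 ± 92.5 to 1708 ± 45.8, and the integrin subunit ITGA8 rose 4.80-fold to 33.9 ± 2.44. The peptide hormone gene ADM rose 4.50-fold to 118 ± 11.8. SMOC1, which encodes a matricellular protein, rose to 64.1 ± 7.65 from 12.6 ± 3.02, and BTN2A2, of the butyrophilin family, rose to 53.1 ± 3.84 from 11.1 ± 3.84. The long non-coding RNAs LINC00484, LINC02362 and ALDH1A3-AS1 rose by log2 fold changes of 2.23, 2.23 and 2.17. The pseudogenes VDAC2P3 and HMGA1P8 were also among the 12 largest rises (log2 fold changes 2.95 and 2.76). Their reads can come from their parent genes, and HMGA1P8 was listed at 0 in 2 control libraries and at 5.78 in the other.

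Among genes with a name and a mean of at least 5, the 12 largest falls on the log2(value + 1) scale included RNF5 and many genes of protein folding and oxidative stress. Their order depended on the pseudocount, and at 0.1 SPARC (-6.25) and HSPA6 (-5.11) fell more than RNF5 (-4.07). The inducible chaperone HSPA6 fell 38.8-fold, from 27.7 ± 4.65 to 0.713 ± 0.185, HSPH1 fell 9.87-fold to 18.3 ± 2.72, and HSPB1 fell 7.95-fold from 1494 ± 240 to 188 ± 26.9. SRXN1, which repairs oxidized peroxiredoxins, fell 5.96-fold to 19.2 ± 0.824, and OSGIN1 fell 5.87-fold to 4.56 ± 0.805. The interferon-induced gene IFIT3 fell 8.63-fold to 1.15 ± 0.192, and the non-coding RNA LUCAT1 fell from 34.2 ± 2.10 to 6.84 ± 1.54. SPARC, a secreted matrix protein, fell to 0.20, 0.24 and 0 in the knockdown libraries from 24.29, 23.66 and 7.70 in the control libraries (log2 fold change -3.94, adjusted p = 4.10e-06). Of the 1290 genes tested, limma called 1260 changed, 718 higher and 542 lower, and the 30 others did not pass. At least 2-fold changes numbered 454 higher and 216 lower (67.8% higher). With the knockdown values divided by the median offset from the authors' fold changes, a check chosen after the data were seen, that split was 350 higher and 324 lower (51.9% higher). In 1749 of the 1877 genes (93.2%) the 2 groups did not overlap, against 10% by chance for unselected genes, and the authors' selection makes this share no independent evidence.

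**Figure D1:**
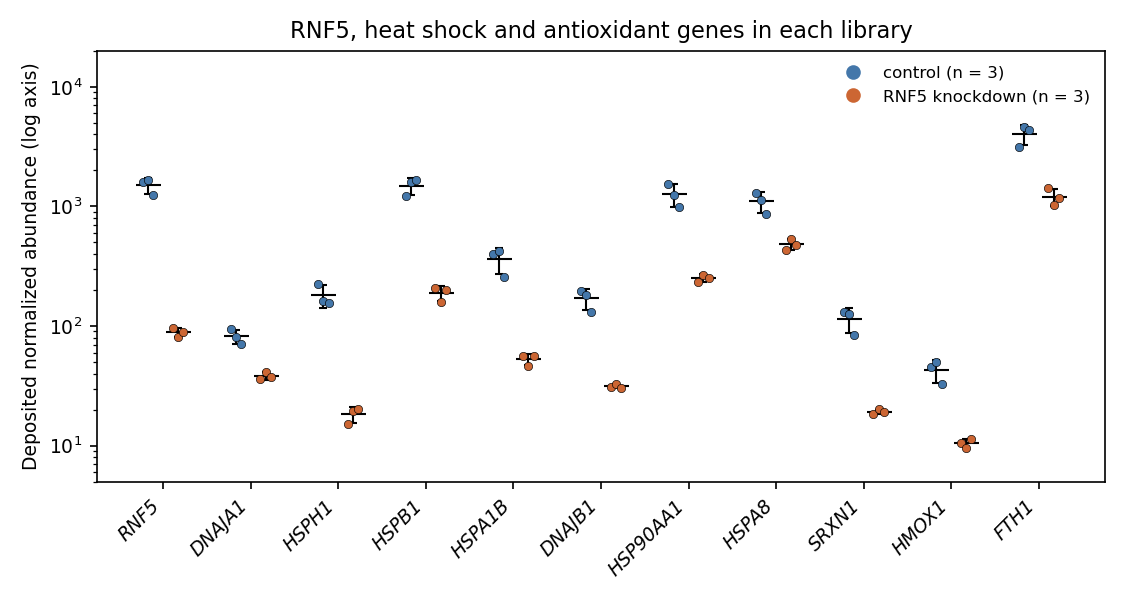
Deposited normalized abundance (log axis) of RNF5, DNAJA1 and 9 heat shock or antioxidant genes in the 3 control and 3 RNF5 knockdown libraries, each point a library, with the mean and SD as bars. The knockdown points lie below the control points for each gene, with RNF5 between 81.35 and 95.40 in the knockdown and between 1248 and 1649 in the control.

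Heat shock genes fell together. Of the 26 genes in the list fixed beforehand, 17 were in the authors' set and all 17 fell, with a median log2 fold change of -1.27. DNAJA1 was 1 of the 17, and its fall (-1.07) was smaller than that median. Most encode cytosolic chaperones, but the list also held HSPE1, the mitochondrial co-chaperonin, and SERPINH1, a collagen chaperone of the endoplasmic reticulum. HSP90AA1, the inducible cytosolic HSP90, fell 5.01-fold from 1259 ± 277 to 251 ± 18.5, and DNAJB1, a co-chaperone of HSP70, fell 5.42-fold to 31.4 ± 1.09. HSPA1B fell 6.83-fold from 360 ± 88.8 to 52.8 ± 5.55, a level that is uncertain because HSPA1A is nearly identical. HSPA8, the constitutive HSP70 and named here after its values were seen, fell from 1099 ± 219 to 483 ± 52.1. All 17 also passed when adjusted over the list alone. Here and for the lists below this had to follow, since each such member had already passed over all genes tested. The direction of the 17 differed from that of the other changed genes, of which 525 were lower and 718 higher (Fisher's exact test, adjusted p = 3.07e-06, range 4.48e-07 to 4.44e-05 over 12 alternatives). The other changed genes included non-coding RNAs and pseudogenes, listed mostly as higher, so part of this difference may follow gene class. The authors chose the genes on these libraries, so the count is not independent evidence of a change, and the other 9 list members have no values here.

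Genes of the NRF2 and antioxidant response fell as well. Of 31 list members, 11 were in the authors' set and all 11 fell, also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.000264, range 6.88e-05 to 0.00162). FTH1, the ferritin heavy chain, fell 3.34-fold from 4036 ± 783 to 1208 ± 192, and the haem oxygenase HMOX1 fell 4.06-fold from 42.7 ± 9.23 to 10.5 ± 0.851. SRXN1 and OSGIN1, both among the 12 largest falls given above, belong to the same list. In the list of ATF4 targets of the integrated stress response, 8 of 43 members were in the authors' set. All 7 that could be tested fell, again with the same number adjusted over the list alone (Fisher's exact test, adjusted p = 0.00400, range 0.00108 to 0.0140). The transcription factor DDIT3 fell from 370 ± 32.6 to 172 ± 1.40, ATF3 from 176 ± 60.5 to 54.7 ± 5.52, and the phosphatase subunit PPP1R15A from 132 ± 31.9 to 57.0 ± 2.84. SLC3A2, the heavy chain of amino acid exchangers, fell from 1313 ± 121 to 558 ± 5.98. The lists share SLC7A11, so they are not separate groups. With the length trend removed, all 7 ATF4 targets and 10 of the antioxidant genes fell, DDIT3 by a log2 fold change of -0.56 in place of -1.10. The authors' selection limits both lists as above. Protein-coding genes of the authors' set were more often lower (752 against 516 higher), so part of both directions may follow gene class. No test within a class was run.

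Genes of G2/M and mitosis formed another group that fell. Of 37 list members, 10 were in the authors' set and all 10 fell, also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.000414, range 6.88e-05 to 0.00220). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 378 ± 26.3 to 138 ± 0.463, and CDC20, an activator of that complex, fell from 181 ± 31.8 to 62.4 ± 2.14. PTTG1, which encodes securin, fell from 95.8 ± 21.9 to 42.0 ± 2.98, and the kinase gene AURKA fell from 146 ± 24.1 to 75.8 ± 4.63. The list of G1/S and DNA replication held 40 genes, of which 2 were in the authors' set and both rose. Of 27 p53 targets, 4 were listed and 3 fell, namely PMAIP1 (log2 fold change -1.24), GADD45A (-1.07) and TNFRSF10B (-0.79). With the length trend removed, a check chosen after the data were seen, all 10 G2/M genes still fell, but UBE2C went from a log2 fold change of -1.44 to -0.81 and PTTG1 from -1.15 to -0.61. The authors picked all these genes on these libraries, so the counts are not independent evidence. Protein-coding genes of their set were more often lower, so part of the G2/M direction may also follow gene class.

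**Figure D2:**
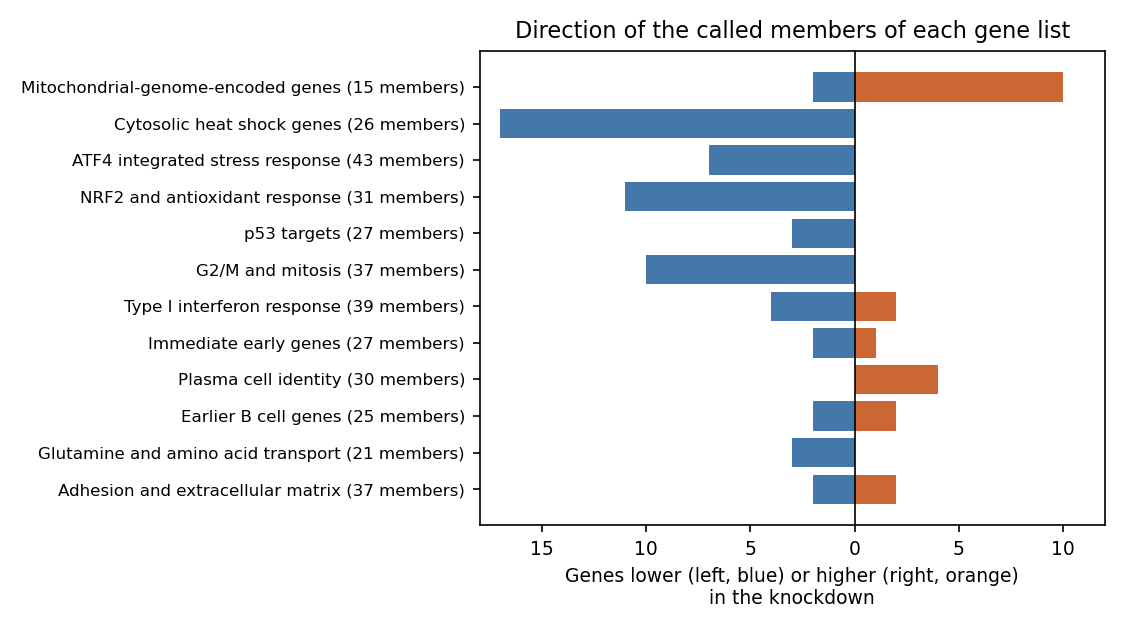
Number of changed genes per fixed list, lower in the knockdown to the left (blue) and higher to the right (orange), for pathway lists with at least 3 changed members, with the size of each list in parentheses. All 17 changed heat shock genes, 11 antioxidant genes, 10 G2/M genes and 7 ATF4 targets lie on the lower side, while the mitochondrial genome list has 10 higher and 2 lower.

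Transcripts of the mitochondrial genome moved in opposite directions by class. All 10 listed mRNAs rose (median log2 fold change 1.72, range 1.17 to 2.05), while both ribosomal RNAs fell (-1.55 for MT-RNR1 and -1.76 for MT-RNR2). MT-CO1, a subunit of cytochrome c oxidase, rose from 2942 ± 392 to 11715 ± 1147, MT-CO2 from 2720 ± 335 to 9688 ± 385, and the complex I subunits MT-ND5 from 1615 ± 198 to 6676 ± 815 and MT-ND6 from 1042 ± 28.8 to 3989 ± 186. MT-RNR2 fell from 15833 ± 2363 to 4636 ± 289 and MT-RNR1 from 2816 ± 578 to 947 ± 46.4, both named because they went against the rest of the list. Together the 10 mRNAs summed to 27122 in the mean control and 80078 in the mean knockdown, and the ribosomal RNAs to 18648 and 5583. All 12 passed adjusted over the list alone and over all genes tested. The share of higher members did not pass against other changed genes (Fisher's exact test, adjusted p = 0.0964). Those genes included non-coding RNAs and pseudogenes, listed mostly as higher, and no comparison with protein-coding genes alone was run. Without 1 knockdown library the share of higher members did pass Fisher's exact test, with adjusted p = 0.0471, 0.0460 and 0.0463 for leaving out replicate 1, 2 and 3 (range 0.0460 to 0.275 over 12 alternatives). The list itself stayed at 10 higher and 2 lower throughout. The changed genes that were higher then numbered 559, 556 and 555 in place of 718, so the pass came from the comparison genes. MT-ND1, MT-ND3 and MT-ND4L were not among the listed genes, and reads can be shared with copies of mitochondrial sequence in the nuclear genome.

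**Figure D3:**
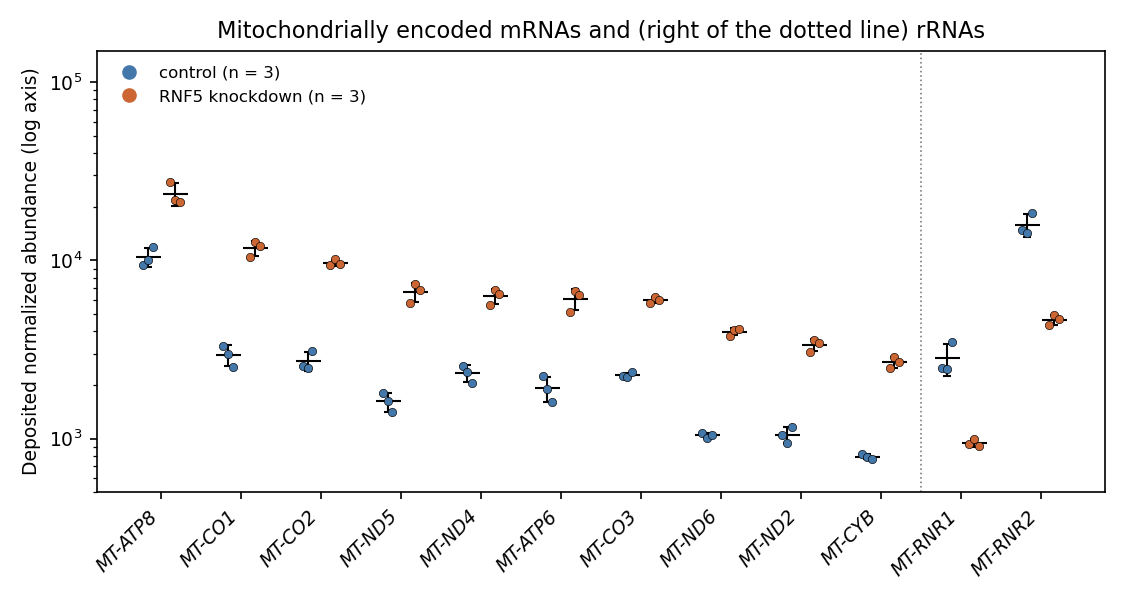
Deposited normalized abundance (log axis) of 10 mitochondrially encoded mRNAs and, right of the dotted line, 2 mitochondrial ribosomal RNAs in the 3 control and 3 RNF5 knockdown libraries, each point a library, with the mean and SD as bars. The knockdown points lie above the control points for each mRNA and below them for MT-RNR1 and MT-RNR2.

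Few nuclear genes of mitochondrial function were in the authors' set. None of the 37 complex I genes, 39 genes of complexes II to V, 20 tricarboxylic acid cycle genes and 22 glycolysis genes was listed, so these have no values here and no statement on their stability can be made. Of 77 mitochondrial ribosomal proteins, 2 were listed and both fell. Of 35 import and chaperone genes 1 was listed and fell, HSPE1, which the heat shock list also counts, and of 16 biogenesis genes 1 was listed and fell. Of 24 dynamics and mitophagy genes 2 were listed and fell. Fatty acid oxidation (19 genes) and the hypoxia response (22 genes) had 1 listed gene each, and both rose.

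The lists closest to the function of RNF5 also held few selected genes. Of 36 genes of degradation at the endoplasmic reticulum, 2 were listed and fell, RNF5 itself being one. Endoplasmic reticulum chaperones (33 genes) had 1 fall and 1 rise, and proteasome subunits (38 genes) had 1 fall. None of the 33 genes of nuclear export and import was listed. Autophagy and lysosome genes (37) had 2 falls, 1 of them in SQSTM1, which the dynamics and mitophagy list also counts. The BCL2 family (18) had 1 fall, in PMAIP1, which the p53 list also counts. Fatty acid synthesis (16) had 2 rises, and cholesterol synthesis (25) and NF-kB targets (28) had 1 rise each. Of 21 genes of glutamine and amino acid transport, 3 were listed and all fell. They were SLC3A2, also an ATF4 target, glutamine synthetase GLUL (log2 fold change -1.54) and the cystine transporter SLC7A11 (-0.88), also in the ATF4 and NRF2 lists. No listed gene came from the replication-dependent histones (21), MYC targets (35) or cytosolic ribosomal proteins (77).

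Markers of the plasma cell lineage rose where they were listed. Of 30 genes, 4 were in the authors' set and all rose, namely ITGB7, ITGA8, the co-stimulatory receptor CD28 (from 6.26 ± 1.01 to 20.0 ± 2.0) and SDC1, which encodes the plasma cell antigen CD138 (from 12.1 ± 2.66 to 35.5 ± 1.16). Genes of earlier B cells went both ways. BLK and CIITA rose (log2 fold changes 1.63 and 1.56), BLNK and CD72 fell (-1.62 and -0.90), and the other listed member of the 25 genes was too low to test. Myeloma driver genes (26) had 1 rise and 1 fall. With fewer than 5 changed members, these lists had no test of direction.

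The type I interferon list was split as well. Of 39 genes, 10 were in the authors' set, which listed 8 as lower and 2 as higher, and 6 were abundant enough to test. Of these, 4 fell, among them IFIT3, IFIT2 (from 2.51 ± 0.566 to 0.10 ± 0.0656) and HERC5 (log2 fold change -1.09), and 2 rose, among them SAMD9 (1.03). The counts were equal when adjusted over the list alone, and the direction of the list did not pass (Fisher's exact test, adjusted p = 0.412, range 0.0817 to 0.679). Of 27 immediate early genes, 5 were listed, 3 as higher and 2 as lower by the authors. EGR1 rose from 0.0367 ± 0.0153 to 1.83 ± 0.270, while ATF3 and DUSP5 (-0.85) fell. EGR3, too low to test, was at 0.0533 ± 0.0681 in the control and 0.613 ± 0.153 in the knockdown, and NR4A1, which did not pass, at 1.27 ± 0.177 and 1.71 ± 0.345. In the adhesion and matrix list (37 genes, 5 listed), ITGB7 and the cadherin CDH2 (1.21) rose, and SPARC and the annexin ANXA1 (-2.20) fell.

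Markers of cells other than LP-1 were mostly absent from the authors' set, which says nothing of their level, since genes at equal levels could not be listed. None of 20 T and NK cell markers, 20 myeloid markers and 17 erythroid and platelet markers was listed. Among 16 fibroblast markers COL1A1 was listed, at 0.593 ± 0.125 in the control and 0.217 ± 0.197 in the knockdown, too low to test. SPARC and ANXA1, which stromal cells also express and which are in the adhesion list, fell to 0.147 ± 0.129 from 18.6 ± 9.40 and to 0.730 ± 0.314 from 6.95 ± 1.45. Among 14 epithelial and packaging cell markers CLDN4 was listed and fell from 2.70 ± 0.735 to 1.36 ± 0.104 (log2 fold change -0.63, limma adjusted p = 0.00675). Control library 3 had the lowest value of the controls in 428 of 598 genes with a mean of at least 5. Knockdown library 1 was the lowest of its group in 333 of these genes. Without control library 3, limma called 1161 genes changed, 709 higher and 452 lower, without knockdown library 1 it called 1076, 559 higher and 517 lower, and 16 or 17 heat shock genes fell whichever library was left out. Longer protein-coding genes were more often higher, with a Spearman correlation of 0.27 between log2 fold change and length across 446 genes, which are not independent replicates. Single libraries also deviated from their own group mean with length. The correlations were 0.55, 0.18 and -0.46 for control libraries 1, 2 and 3. For knockdown libraries 1, 2 and 3 they were -0.41, 0.36 and 0.05. Libraries of the same group thus differed in this trend, and it cannot be assigned to the knockdown.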

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

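The rescaling by the median offset from the authors' fold changes, the removal of a length trend and the direction tests of the lists were chosen after the data were seen, and the other alternatives before. The 58 named genes with a test kept their direction and their side of the threshold in all 681 gene-by-alternative values that could be had. All 58 had passed the threshold with groups that did not overlap. Only the rescaling and the removed length trend could therefore have reversed a direction, and this count is no independent evidence of stability. HSPA6, SPARC, IFIT2 and BLNK did not pass the filter without any one control library, nor EGR1 without any one knockdown library, so these 5 genes have no value there. RNF5 ranged from a log2 fold change of -4.23 to -3.57 and DNAJA1 from -1.23 to -0.94 over the alternatives. Without 1 library at a time, RNF5 ranged from -4.19 to -3.98, DNAJA1 from -1.16 to -0.97, the changed genes from 1076 to 1161, those changed at least 2-fold from 606 to 644 and the lists with a direction from 4 to 5, the mitochondrial list being the added one when a knockdown library was left out. Part of these lower counts comes from the filter, which fewer genes passed with 5 libraries. The count of at least 2-fold changes depended on the pseudocount, with 1030 genes at 0.1 (692 higher, 338 lower) and 238 at 5 (163 higher, 75 lower) against 670 at 1, as a larger pseudocount shrinks the folds of low genes by construction. No filter gave 1785 changed genes of 1874, and the stricter threshold of 0.01 gave 1199. The rescaling gave 1249 and the removed length trend 1080 of 1187 genes tested. No gene called in both the reported fit and an alternative changed sign. With a replicate block, 1272 genes changed and 670 at least 2-fold. Libraries of the same number did not deviate together (correlations across 598 genes -0.32, -0.12 and -0.15), which gave no sign of pairing. Pairing cannot be excluded, because the genes were selected on these libraries and the labels do not state it. The planned count-based alternatives and the set test with an estimated correlation were not run, because the table held no counts and only selected genes. Depth is unknown and sets no stated limit.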

Other observations

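The tests of unequal ribosomal RNA removal, of a single scaling factor and of handling stress, the list of assembly factors and all Fisher's exact tests were chosen only after the results were seen. The genes in the next paragraph were also chosen after their values were seen, and all adjusted p-values there come from limma.

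Other single genes of interest were found among the selected genes, with no list or set test behind them. The near-identical paralogs FAM72A, FAM72B, FAM72C and FAM72D all fell (log2 fold changes -1.14, -1.34, -1.59 and -1.74), although their reads cannot be told apart with certainty. The metallothioneins MT2A and MT1X, which bind zinc and copper, fell by log2 fold changes of -1.52 (adjusted p = 0.000968) and -1.09 (adjusted p = 0.00627). Among genes of the mitochondrial inner membrane, the calcium channel MCU fell from 18.9 ± 2.83 to 9.18 ± 0.597 and the pyruvate carrier subunit MPC1 from 212 ± 27.2 to 115 ± 6.46, and CHCHD10 of the intermembrane space fell from 128 ± 27.2 to 58.2 ± 15.3. ARRDC4, a paralog of TXNIP that like it is induced by the glucose sensor MondoA, rose as TXNIP did, from 0.720 ± 0.269 to 5.21 ± 0.174 (log2 fold change 1.86). HGF, a growth factor secreted by myeloma cells, rose from 0.763 ± 0.225 to 5.0 ± 0.294, the transcription factor ETS1 from 6.92 ± 1.46 to 26.9 ± 1.95, and the chemokine receptor CCR3 from 0.373 ± 0.0777 to 4.66 ± 0.414. The large cytoskeletal genes FLNA and AHNAK rose by log2 fold changes of 1.52 and 1.43.

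By gene class, the authors' set held 516 protein-coding genes listed as higher and 752 as lower, but 187 higher and 83 lower among long intergenic and antisense RNAs and 69 higher and 19 lower among pseudogenes. Within 1.5 Mb of RNF5 on chromosome 6, in the order of the GENCODE annotation, 12 other genes were listed, 11 lower and 1 higher (Fisher's exact test on the authors' directions, unadjusted p = 0.00626), and the heat shock genes HSPA1A, HSPA1B and HSPA1L were among them. HSPA1A and HSPA1B are nearly identical and already counted in the fall of the heat shock list. These neighbours are thus not independent, and no local effect at RNF5 is shown. RNF5 itself ranked 13 of the 1877 listed genes by its mean in the control libraries. The authors' values of PRKCH, TIGAR and COL19A1 were lower in the knockdown while the library means were higher, for example 0.927 ± 1.21 against 0.563 ± 0.552 for PRKCH.

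The real grouping gave 1260 changed genes, and the highest of the 9 other splits of the 6 libraries into 3 and 3 gave 1. For changes of at least 2-fold the values were 670 and 1, and for lists with a direction 4 and 0. In each case 1 of the 10 splits, the real one, gave a result as large. With 10 splits no share under 0.05 can be reached, and the genes had been chosen on the real grouping.

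The first pattern was the rise of mitochondrial mRNAs with a fall of mitochondrial ribosomal RNAs in the knockdown. A single scaling factor per library would move both classes alike, but their median log2 fold changes differed by 3.38. The length trend was fitted on selected nuclear protein-coding genes and carried over to mitochondrial transcripts, where it may differ. Among such nuclear genes, lower ones were shorter (median 2746 bases, against 3878.5 for higher ones). Its removal therefore favoured a rise of short transcripts. With it removed the median of the mRNAs was 2.28 and that of the ribosomal RNAs -1.19. This nuclear trend thus did not account for the rise, but a trend particular to mitochondrial transcripts stays open. For the ribosomal part, unequal removal of ribosomal RNA during library preparation may be the source, and it cannot be told apart from a change in the cells because 0 other ribosomal RNA genes of the set had a value above 0. The authors listed the ribosomal RNA gene RNA5S14 as lower (their log2 fold change -4.12), but it was at 0 in every library and cannot decide this. A changed balance of the 2 classes after loss of RNF5 was not tested and stays open, and the 7 listed nuclear copies of mitochondrial genes, all higher (summed mean 166 to 504), cannot serve as separate evidence because their reads may be shared.

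The second pattern was the fall of the heat shock genes. At least 16 of the 17 genes were called lower whichever library was left out. Most listed genes, selected as changed, were also called in such fits. They were 1161 of 1188 tested without control library 3 and 1076 of 1130 without knockdown library 1. The count is therefore no independent evidence against an aberrant library. With the length trend removed all 17 fell, in a fit that called 1080 of 1187 genes. Their median log2 fold change was then -1.13 in place of -1.27, so this trend accounted for little of the size of the fall. Acute stress of the control cultures at harvest may also raise such genes, and it stays open because 3 immediate early genes were called, ATF3 and DUSP5 lower and EGR1 higher, too few to decide, while the authors listed 3 as higher (EGR1, EGR3 and NR4A1) and 2 as lower. No biological explanation was tested, and an effect of RNF5 depletion cannot be told apart from a stressed control in this design, which has no untreated cells.

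The last pattern was a fall of assembly factors of oxidative phosphorylation, from a list of 56 genes written after the data were seen. Of 7 listed, 6 fell, among them NDUFAF2, NDUFAF4, COA6 and COX17, and the median length of the 7 was 1196 bases. Control library 3 had the highest control value in each of the 7. COX17 was at 449.5 there, against 217.44 and 228.89 in control libraries 1 and 2. FMC1 was at 48 there, against 21.96 and 27.98. The size of these falls thus leaned in part on control library 3. With the length trend removed 4 of the 7 fell (NDUFAF2, NDUFAF4, COA6 and COA8), COX17 and FMC1 lost their calls (COX17 from -0.97 to -0.17, adjusted p = 0.345), and the median log2 fold change went from -0.97 to -0.39, so part of the pattern may follow transcript length. The 4 of 7 genes met the bound written against the length trend, but by less than counting error, and the trend therefore cannot be told apart from a change in these genes.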
